A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

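Per the labels, fission yeast (Schizosaccharomyces pombe) cells with HA-tagged Cdk11 were grown at 32 °C in rich medium to mid-log phase and fixed for 10 min in 3% formaldehyde. Their chromatin was sheared to about 500 bp and precipitated with an anti-HA monoclonal antibody. The DNA was amplified by ligation-mediated PCR, labelled, and hybridised against input DNA on 4 Agilent arrays of the 4x44k format. The 4 arrays form 1 group. Per the labels, replicates 1 and 3 came from the first of 2 independent immunoprecipitations and replicates 2 and 4 from the second, so n = 2 and the duplicate arrays of each are technical. No untagged or mock sample was analysed here, and no dye swap is among the 4 arrays.

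Each array has a deposited scanner file with spot intensity values for the red (Cy5) and green (Cy3) channels. Per the file headers these are mean foreground and median local background values, and no header names a normalization. Per the file headers, the same files give the percent of each spot's pixels above local background and the percent that were saturated. They also give, as a fraction per the file headers, the squared correlation of both channels over the pixels of a spot. The format is that of GenePix, so the processed signals of Agilent's own software, which the design fixed before the data were examined had assumed, were replaced by the mean foreground signals as given. The authors' deposited value table holds log2 ratios whose scale, centring and direction no header states. Set against each array's scanner values, it ran as log2(Cy5/Cy3) of the foreground signals after a loess fit, with r from 0.989 to 0.998 and slopes from 0.995 to 1.00. Its medians for replicates 1 to 4 were 0.008, -0.004, -0.014 and -0.013. It was used as an alternative with its sign turned, and how the authors made it is not given in the sources used here.

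The value tested was log2(Cy3/Cy5) of the foreground signals, centred on each array's median probe, with no background subtraction, loess or quantile step. A value of 0 is therefore the median probe of an array, not an absence of the protein. Control spots and spots that the scanner software marked as poor were left out, but spots marked only for saturation were kept, where the squared pixel correlation exceeded 0.3. This removed 16.3, 5.28, 8.05 and 1.00% of the 42707 genomic probes from replicates 1 to 4. A probe counted as well above background where at least 50% of its pixels passed the scanner's background bound in both channels. That held for 29339 probes on all 4 arrays, and 185 were saturated on at least 1 array. The log ratio correlated with spot brightness at r = -0.64, -0.47, -0.55 and -0.63 on replicates 1 to 4, and with probe GC content at 0.01, -0.04, -0.04 and -0.18. The number of arrays limits the precision of every value.

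The array files name no genome build. Probe coordinates were checked against the ASM294v3 assembly in windows of 100000 bp, by the correlation of probe brightness with the GC content of the reference at shifts of up to 10000 bp. Of 127 windows 107 matched, with r of at least 0.2 unshifted and the best shift at most 250 bp, and they hold 36405 probes (85.2%). The 19 windows of chromosome I from 3.7e+06 bp onward, with 6236 probes, had a median best shift of 6120 bp, so no gene was named there. The 66 mitochondrial probes were not matched either. Coordinates are printed only as the array files give them, and ASM294v3 served only for names and for which genes lie at or beside a probe. Of the 5124 coding genes annotated, 4210 lay on matched coordinates.

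Duplicate arrays were averaged, and each immunoprecipitation entered limma (lmFit and eBayes, two-sided, against 0) once. P-values were adjusted by Benjamini-Hochberg and calls made at 0.05. For probes limma estimated an infinite prior, so all probes shared 1 variance. The same held for ORF values after loess, where all genes shared 1 variance. ORF values are means over the probes inside the coding span of a gene with at least 2 such probes. Upstream values cover the 500 bp before the start codon, often with 1 or 2 probes, and can include probes inside a neighbouring gene. Non-coding genes were extended by 250 bp on both sides, so their values can share probes with neighbouring genes. Lists of non-coding genes were compared with the ORF values of coding genes, so their differences can mix the kind of window with the kind of gene. Regions are runs of at least 3 neighbouring probes, centres at most 1000 bp apart, each at least 1.5-fold from the median in the same direction in both immunoprecipitations. They carry no test, and the count in the opposite direction stands beside each count as the background. Intervals are 95% intervals from 2000 bootstrap draws of 50 kb blocks of the genome, with fewer draws for codon adaptation. They describe these arrays, since genes are not replicates. Gene lists, 25 in all, were fixed before the data were examined and tested with camera of limma at a preset correlation of 0.01. They were tested again with an estimated correlation and by rotating the gene values along the genome. The estimated correlation rests on 2 immunoprecipitations, which leave 1 residual degree of freedom. Almost no list could pass that version, so a call lost there decides nothing. With the preset correlation the degrees of freedom come from the number of genes, so those p-values treat genes as replicates. The list of Tf2 retrotransposons had no measured member, and the probes of the mitochondrial genome, a further list, entered no list test.

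Named genes follow a rule: the 12 genes with the highest ORF values, the 6 with the highest upstream values, the 3 members of each list with the largest ORF value in either direction, the 6 longest regions, cdk11 and lcp1. Apart from cdk11 and lcp1, each had the same sign on all 4 arrays over the part it was chosen for, and the genes with the highest ORF values had at least 3 ORF probes. The rule, fixed for IP over input, took 12 genes at the upper end of the ORF values and 6 at the lower end. Because the direction of the dyes was not settled, it was applied both ways after the data were seen, to 12 genes at each end of the ORF values and 6 at each end of the upstream values and regions. Genes outside the rule are named where a count was 5 or fewer, and the text says that they were chosen after their values were seen. No coding gene named by the rule shared its ORF probes with an overlapping coding gene.

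The per-gene test was tested on simulated data for the 3848 genes of the ORF comparison. Of 50 genes given a log2 ratio of 0.5 it recovered 0%, of 50 at 1 it recovered 80%, of 50 at 1.5 it recovered 100% and of 50 at 2 it recovered 98%, with 0 false calls. The simulated noise was each probe's spread around its own mean over the arrays, so it nearly cancelled in the mean of both immunoprecipitations. False calls could hardly arise, so neither their number nor the recovered shares measure the error rate on the real arrays. Alternatives were normexp background correction (offset 50), loess within arrays, centring on the mode, a filter on dim probes, removal of saturated probes, the deposited value table, a correction for GC content, other windows, thresholds and variance models, and leaving out each array or immunoprecipitation. Another 3 were added after the data were seen: keeping the marked spots, subtracting the local background, and loess followed by the GC correction. The software was R 4.3.3 with limma 3.58.1 and data.table at version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.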

Results

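Chromatin immunoprecipitation on tiling arrays was used to map HA-tagged Cdk11, a cyclin-dependent kinase that pairs with an L-type cyclin, across the genome of fission yeast, in a study of this kinase and Mediator, the coactivator complex of RNA polymerase II. The data are 4 arrays of 1 group, made from 2 independent immunoprecipitations with 2 hybridisations each, with input DNA in the other channel. Each array held 42707 genomic probes with a median length of 60 nt and a median spacing of 264.5 bp. The median Cy5 signal was 2889, 3522, 3551 and 4862 on replicates 1 to 4, and the median Cy3 signal 5371, 5097, 6341 and 6028. Cy5 signals were well above local background at 80.2, 91.7, 88.2 and 97.8% of the probes, and Cy3 signals at 99.6 to 99.8%. Over the negative control spots the median Cy5 signal was 4.46, 5.63, 5.45 and 14.1 times as high on replicates 1 to 4, and the median Cy3 signal 7.81, 4.99, 5.19 and 4.02 times.

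The labels give Cy3 for the immunoprecipitated DNA and Cy5 for the input, whereas the authors' deposited ratios run as Cy5 over Cy3. The direction of immunoprecipitate over input is therefore not settled here. All values are log2(Cy3/Cy5) relative to the array's median probe, so a negative value is higher in Cy5, and genes are described by the channel in which they were higher. Where Cy3 holds the immunoprecipitate a negative value is a depletion, and where Cy5 holds it the same value is an enrichment.

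Which parts of the genome departed from the rest was asked first by runs of neighbouring probes. The longest region higher in Cy5 lay on chromosome II at 4444227 to 4449444 and covered pho84, which encodes a phosphate transporter, and pho1, which encodes an acid phosphatase. Its 22 probes averaged -2.02, or 4.06-fold higher in Cy5, with -2.21 in the first immunoprecipitation and -1.83 in the second (n = 2). Further regions covered the translation elongation factor gene tef3 (III, 1685674 to 1689166, 3.30-fold), the methionine synthase gene met26 (I, 1478589 to 1481247, 3.94-fold), and knh2 with the ribosomal protein gene rpl2302 (III, 1309928 to 1312563, 2.66-fold). The other long ones, at 3865217 to 3869909 (5.06-fold) and 3881982 to 3884681 (3.74-fold) on chromosome I, lie where array coordinates did not match the reference, so no gene is named.

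**Figure D1:**
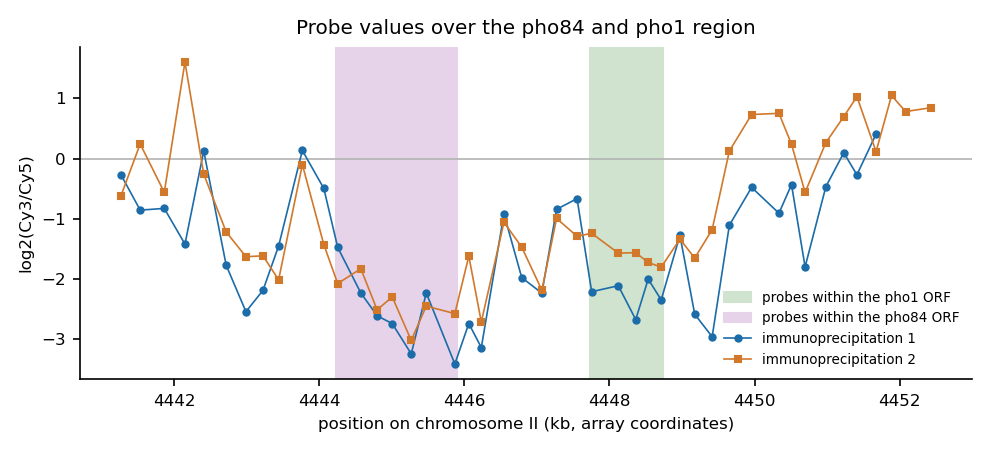
Log2(Cy3/Cy5) of each probe (y axis) against its position on chromosome II in the array files' coordinates (x axis) around pho84 and pho1, with a line per immunoprecipitation and the ORFs shaded. Over the 22 probes of the region the means were -2.21 and -1.83.

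In all, 202 regions were higher in Cy5, with a median length of 844 bp, a median of 2.56-fold and a total of 230 kb. Of these, 148 overlapped a coding gene and 38 lay where no gene could be assigned. In the mirrored direction 14 regions were higher in Cy3, with a median of 578.5 bp and 1.96-fold, 7 over a coding gene and 3 not assigned. The longest of these lay at 2919727 to 2920589 on chromosome I with no coding gene (2.13-fold), over atp11, an ATP synthase assembly factor gene (I, 1440552 to 1441377, 1.91-fold), and over gst2, a glutathione S-transferase gene (III, 2294898 to 2295661, 2.15-fold). The next were at 4724160 to 4724914 (2.00-fold) and 4599017 to 4599734 (1.96-fold) on chromosome I, with no gene assigned, and at 41497 to 42211 on chromosome II with no coding gene (1.73-fold). Regions carry no test. Split into Cy3 and Cy5, the counts were 24 and 96 after loess, 23 and 92 in the deposited value table, 16 and 81 after loess with the GC correction, and 56 and 276 after normexp, and without replicate 4 the Cy3 count was 37.

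Of 41237 single probes, limma called 953 higher in Cy5 and 93 higher in Cy3. At least 1.5-fold in both immunoprecipitations were 2757 probes higher in Cy5, against 1440 from the product of the shares, and 1718 higher in Cy3, against 1066, while 1298 went in opposite directions. The called split depends on the scaling: it was 1706 in Cy3 and 2806 in Cy5 after loess, 2276 and 3208 in the deposited value table, and 1283 and 2345 after loess with the GC correction. Without replicate 3 the calls were 274 in Cy5 and 1 in Cy3, without replicate 2 they were 588 and 46, and without replicate 4 the Cy3 count was 30.

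Over open reading frames (ORFs), the genes highest in Cy5 were pho84 at -2.48 ± 0.12 (SD, n = 2) and adh1, the alcohol dehydrogenase gene, at -2.48 ± 0.43. Glycolytic and fermentative genes among the 12 were fba1 (aldolase) at -2.22 ± 0.58, pdc101 (pyruvate decarboxylase) at -2.18 ± 0.33, pgk1 (phosphoglycerate kinase) at -2.07 ± 0.33 and eno101 (enolase) at -1.96 ± 0.51. Genes of the cell surface and of transport among them were mfs3, annotated as a spermidine family transporter, at -2.32 ± 0.54, psu1, annotated as a beta-glucosidase, at -2.29 ± 0.27, ecm33, a cell surface protein, at -2.19 ± 0.22, and ght8, a hexose transporter, at -2.10 ± 0.49. The others were met26 at -2.19 ± 0.13 and ssa2, an Hsp70 chaperone gene, at -2.11 ± 0.29. Adjusted p from limma ran from 1.16e-06 for pho84 to 1.09e-05 for eno101. The 12 were chosen among genes with the same sign on all 4 arrays, so that sign adds no support.

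At the Cy3 end the values were smaller. The genes isa2, an iron-sulfur protein, at 0.90 ± 0.43 (SD, n = 2) and trm141, an annotated methyltransferase, at 0.89 ± 0.19 came first, followed by SPAC16C9.01C, a carbohydrate kinase, at 0.85 ± 0.11. RNA-processing genes were tgs1, the cap methyltransferase, at 0.77 ± 0.004, thg1, the tRNA guanylyltransferase, at 0.76 ± 0.05, and cbc3, a cap-binding protein, at 0.71 ± 0.09. The other called genes among the 12 highest in Cy3 with the same sign on all 4 arrays and at least 3 ORF probes were mug65 (0.74 ± 0.40), kin17 (0.71 ± 0.26) and SPCC777.03C (0.69 ± 0.20). Adjusted p for these 9 ran from 0.00771 for trm141 to 0.0458 for SPCC777.03C. The COP9 signalosome gene csn5 (0.66, adjusted p = 0.0604), the ESCRT gene dot2 (0.66, 0.0694) and the arylsulfatase gene SPBPB10D8.02C (0.66, 0.111) did not pass. Without replicate 3 mug65 had 0.44 and SPCC777.03C 1.11, and SPBPB10D8.02C passed at 1.11.

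Of 3848 genes tested over the ORF, 176 were higher in Cy5 and 21 in Cy3, and across genes the immunoprecipitations correlated at r = 0.52. All 4 arrays had the same sign at 967 genes, or 25.2%. Independent arrays with no effect would give 12.5%, but duplicate arrays share a preparation, so the share without an effect can be higher. All 12 genes highest in Cy5 passed the test after loess too, at smaller values, -1.22 for pho84 and -0.47 for ght8, whereas the deposited value table lost psu1, met26, ecm33 and ght8. Of the 9 named Cy3 calls 4 were lost after loess, those of isa2 (0.38, adjusted p = 0.0619), SPAC16C9.01C (0.37, 0.0710), thg1 (0.31, 0.142) and kin17 (0.20, 0.388), and all 9 were lost with centring on the mode, in the deposited value table and without replicate 4. The Cy3 and Cy5 counts were 275 and 216 after loess, with 92 Cy5 genes shared, 186 and 237 after loess with the GC correction, 39 and 62 in the deposited value table, 57 and 219 after normexp, and 0 and 143 with centring on the mode, where limma had 45 Cy3 genes at an unadjusted p under 0.05. Without replicates 2, 3 and 4 the Cy5 count was 99, 116 and 107, and the Cy3 count 3, 9 and 6. For the ORF test after loess limma estimated an infinite prior, against 16.0 prior degrees of freedom before it. Counts and calls over ORFs after loess thus mix the scaling with a change of variance model.

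Among the gene lists, ribosomal proteins, translation factors, glycolysis and fermentation, and chaperones were called higher in Cy5 than other genes by camera, but not with an estimated correlation (adjusted p = 0.482 for each). With 2 immunoprecipitations almost no list could pass the latter version. Of 138 ribosomal protein genes 61 were measured, since 18 lay on unmatched coordinates and 59 had fewer than 2 ORF probes. Of these 61, 41 passed the test higher in Cy5 (56 adjusted over the list alone) and 0 in Cy3, with a median of -0.94 (-1.14 and -0.84 in the immunoprecipitations). Examples were rps2 at -1.84, rps3 at -1.64 and rpp102 at -1.61. Of 14 measured glycolysis and fermentation genes 9 passed (12 adjusted over the list alone), with a median of -1.03. Translation factors had 2 of 5, tef3 at -1.75 and tef5 at -1.04, the latter lost without replicate 3 at -0.98 (2 adjusted over the list alone), and chaperones 5 of 18 (8 adjusted over the list alone), among them sks2 at -1.86 and the mitochondrial chaperonin gene mcp60 at -1.83. Of the core histone genes 1 was measured, htb1 at -1.68 (adjusted p = 1.5e-05), and no list test was run on this single ORF value. With upstream values the core histone list was called in Cy5, at -0.72 against other genes (adjusted p = 0.000331).

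Lists of 4 kinds of small or ribosomal RNA genes were also called higher in Cy5 by camera, against the ORF values of coding genes. Few of their tRNA and rRNA genes passed the test, though. None of these calls held with an estimated correlation (adjusted p = 0.482 for each). Small nucleolar RNA genes, which guide rRNA modification, had a median of -0.77, and 18 of 57 passed (36 adjusted over the list alone), led by snoU14 at -2.86, snoZ16 at -2.59 and snoZ4 at -2.40. With their flanks these genes can share probes, yet each entered the counts and the list test separately. The snoZ4 gene lies in a region of 6 probes higher in Cy5 that also overlaps other snoRNA genes and a coding gene. The region over snoU14 overlaps a coding gene too, and that over snoZ16 overlaps none. Of 6 spliceosomal and other small nuclear RNA genes 3 passed (4 adjusted over the list alone), namely snu2 at -2.29, snu4 at -1.21 (lost without replicate 2 at -0.96) and, chosen after its value was seen, snR48 at -1.13. The snR48 value rests on 1 probe, and the gene overlaps a region higher in Cy5 that covers rps3. Among the others snu5 had -0.93 (adjusted p = 0.111). Also named after their values were seen, snu1 at -0.18 and snu6 at 0.21 did not pass (limma adjusted p = 0.782 and 0.771). Without replicates 1, 3 and 4 snu5 had -0.39, -1.47 and -2.02 and passed in the latter 2, and without replicate 4 the snRNA list moved from -0.85 to -1.37 against other genes. Transfer RNA genes had a median of -0.37, with 2 of 119 past the test (3 adjusted over the list alone), SPBTRNAGLY.05 at -1.41 and SPBTRNALEU.09 at -1.34, both lost without replicate 2 at -1.16 and -1.03. Ribosomal RNA genes had a median of -0.40, and 3 of 32 passed, SPRRNA.39 at -1.33 and SPRRNA.26 and SPRRNA.16 at -1.20, both lost without replicate 3 at -1.09 and -0.84 and the latter without replicate 2 at -0.97. Adjusted over the list alone there were 10 in Cy5 and 1 in Cy3, namely SPRRNA.31 at 0.76, chosen after its value was seen.

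Another 4 lists were called in Cy5 by camera but not with an estimated correlation (adjusted p = 0.482 for each). Membrane ATPase and transporter genes had 4 of 13 past the test (7 adjusted over the list alone) with a median of -0.49, including the hexose transporter gene ght5 at -1.29. Nucleotide and amino acid synthesis genes had 4 of 14 (8 adjusted over the list alone) and a median of -0.53, with sam1, S-adenosylmethionine synthetase, at -1.53 and gln1, glutamine synthetase, at -1.19. Cell separation and mitotic genes had 3 of 11 (6 adjusted over the list alone) and a median of -0.57, with the endoglucanase gene eng1 at -1.26, slp1 at -1.23 and cfh4 at -1.02. Stress response genes had 3 of 12 (5 adjusted over the list alone) and a median of -0.21, with superoxide dismutase sod1 at -1.64, peroxiredoxin tpx1 at -1.34 and glycerol-3-phosphate dehydrogenase gpd1 at -1.09. The calls of eng1, slp1, cfh4, tpx1, ght5 and gln1 were lost after loess. Leaving out replicate 3 ended the call over the ORF of gpd1 (-1.003) and that of cfh4 (-1.01), and leaving out replicate 2 that of cfh4 (-0.96).

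By camera these 12 lists were called higher in Cy5 than the other genes and 0 were called higher in Cy3, where the smallest unadjusted p was 0.0591, for long non-coding RNA genes. Adjusted p was 1.51e-42 for ribosomal proteins, 1.65e-31 for snoRNA, 2.21e-14 for glycolysis, 1.07e-08 for tRNA, 5.15e-08 for chaperones, 2.05e-07 for rRNA, 4.2e-06 for transporters, 1.33e-05 for nucleotide and amino acid synthesis, 2.74e-05 for snRNA, 0.00152 for cell separation, 0.002 for stress response and 0.00723 for translation factors. None of the 12 held with an estimated correlation, where adjusted p = 0.482 for each of them and the smallest unadjusted p was 0.0861, for ribosomal proteins. Even lists with a negative estimated correlation lost the call, such as translation factors (-0.2, unadjusted camera p = 0.208). Since that version rests on 2 immunoprecipitations, almost no list could pass it, and it decides nothing about these calls. The calls with the preset correlation take their degrees of freedom from the number of genes, which are not replicates. Their p-values therefore do not measure the spread between immunoprecipitations. Estimated correlations of the 12 lists ran from -0.2 for translation factors to 0.333 for snRNA genes, against the preset 0.01. After loess the cell separation (-0.09, adjusted p = 0.409), stress response (-0.17, 0.0812) and nucleotide and amino acid synthesis (-0.17, 0.0554) lists did not pass, while ribosomal proteins moved from -0.88 to -0.47 against other genes. With upstream in place of ORF values glycolysis (adjusted p = 0.185), translation factors (0.683), stress response (0.490), cell separation (0.404) and nucleotide and amino acid synthesis (0.899) did not pass. Chaperones then lay 0.06 above other genes, which did not pass either. The snoRNA, tRNA, rRNA and snRNA lists have no upstream values, so they kept their own values and only the comparison genes changed.

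**Figure D2:**
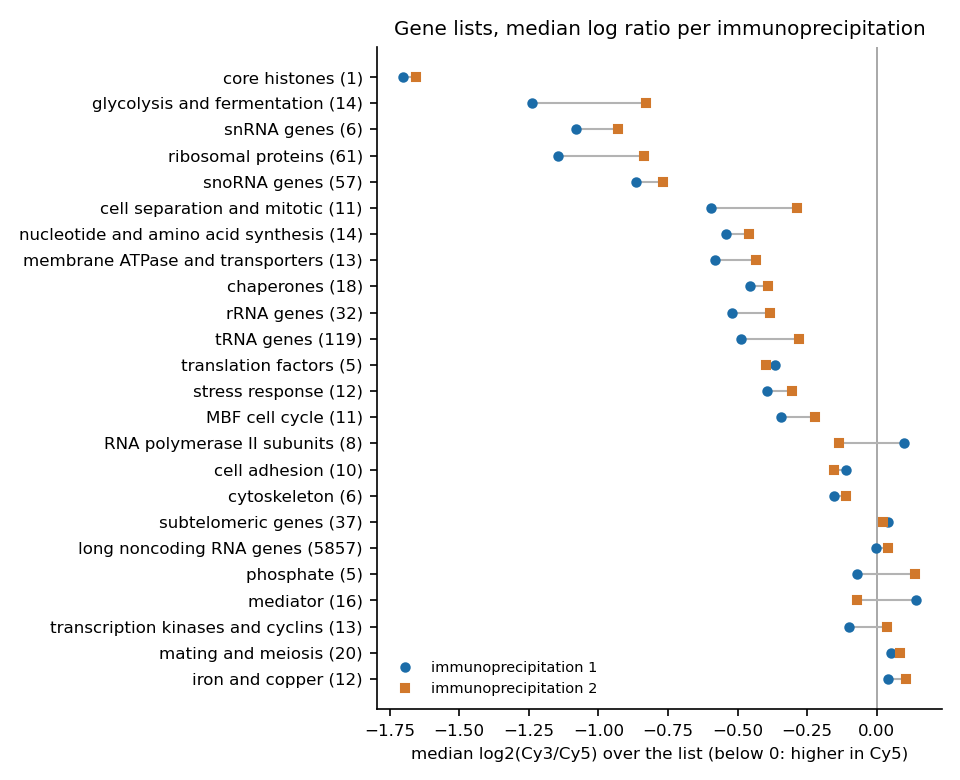
Median log2(Cy3/Cy5) of each gene list (x axis) by list with its number of measured genes (y axis), with a point per immunoprecipitation. Apart from the single core histone gene, glycolysis (-1.03), snRNA (-1.03) and ribosomal protein genes (-0.94) lie farthest toward Cy5.

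The remaining lists were not called. The phosphate list had 2 of 5 genes past the test, pho84 and pho1 (-1.93), and csk1 at 0.57 passed only adjusted over the list alone (2 in Cy5 and 1 in Cy3); its median was 0.05 while its mean lay at -0.66 against other genes (adjusted p = 0.086). That list was called in Cy5 by rotation along the genome (adjusted p = 0.00299), after the GC correction (-0.65, 0.00577), after normexp (-0.68, 0.0170), over probes well above background (-0.62, 0.0489), with upstream values (-0.57, 0.0296) and without replicate 3 (-0.74, 0.0115). With an estimated correlation it was not called (adjusted p = 0.482). Iron and copper genes had 1 of 12, the copper transporter gene ctr4 at -1.74 (1 adjusted over the list alone), with sib2 at 0.44 and fep1 at -0.39 not past it (list adjusted p = 0.528), though sib2 passed after loess at 0.57 (adjusted p = 0.00183). Targets of the MBF cell-cycle factor had 1 of 11, tos4 at -0.75 (1 adjusted over the list alone, list adjusted p = 0.182), lost after loess and when any 1 of the 4 arrays was left out, at -0.60, -0.53, -0.90 and -0.96 without replicates 1 to 4. Cytoskeletal genes had 1 of 6, actin act1 at -1.77 (1 adjusted over the list alone, list adjusted p = 0.269), and cell adhesion genes 1 of 10, mbx2 at -0.91, lost after loess and without replicate 2 at -0.78 (1 adjusted over the list alone, list adjusted p = 0.366), though that list turned toward Cy3 after loess, at 0.24 (adjusted p = 0.0169). Mating and meiosis genes had 0 of 20 past limma's test (0 adjusted over the list alone), with isp3 at 0.59, mfr1 at 0.43 and mde2 at 0.43 (list adjusted p = 0.145). After loess isp3 passed at 0.48 (adjusted p = 0.0127) and mfr1 at 0.46 (0.0170). Subtelomeric genes had 2 of 37 in Cy5, again pho84 and pho1, and 1 in Cy3, SPAC212.04C at 0.81, lost without replicates 3 (0.78) and 4 (0.67) (the same counts adjusted over the list alone, list adjusted p = 0.415). Of 5857 long non-coding RNA genes 68 were higher in Cy5 and 3 in Cy3 (52 and 2 adjusted over the list alone), led by SPNCRNA.2047 at -2.69, SPNCRNA.7609 at -2.20 and mamRNA at -2.20 (list adjusted p = 0.097). That list was called in Cy3 by rotation (adjusted p = 0.000598), with marked spots kept (0.10), after subtracting the local background (0.10) and without replicate 2 (0.08), and lay at -0.07 after loess, not called. With an estimated correlation it was not called either (adjusted p = 0.482). The Cy3 ones, chosen after their values were seen, were SPNCRNA.5478 at 1.15, SPNCRNA.2706 at 1.39 and SPNCRNA.3394 at 1.45. The values of SPNCRNA.2706 and SPNCRNA.3394 each rest on 1 probe, which also gives the upstream value of iwr1 and of srb8, respectively.

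Whether Cdk11 and Mediator genes themselves stood apart was examined in the same way. The cdk11 ORF had 0.08 ± 0.18 (SD, n = 2, limma adjusted p = 0.903), and lcp1, the L-type cyclin gene, 0.15 (adjusted p = 0.792). Without replicates 1, 2 and 4 cdk11 had 0.01, -0.07 and 0.23, and without replicate 4 lcp1 had 0.08. Of 16 Mediator subunit genes 0 passed over the ORF by limma (0 adjusted over the list alone), with a median of 0.05, at 0.14 and -0.07 in the immunoprecipitations, and no member had the same sign on all 4 arrays (list adjusted p = 0.365). Subunits of RNA polymerase II had 0 of 8 (0 adjusted over the list alone), with rpb1 at -0.37 and rpb5 at -0.36; their median was -0.13 and their mean 0.03 above other genes (list adjusted p = 0.94). After loess rpb5 passed at -0.44 (adjusted p = 0.0249), and without replicates 1 and 3 it had -0.14 and -0.58. Transcription kinases and cyclins had 0 of 13 (0 adjusted over the list alone), with csk1 at 0.57, mcs6 at -0.50 and mcs2 at -0.46 (list adjusted p = 0.497). After loess mcs2 passed at -0.69 (adjusted p = 9.7e-05) and csk1 at 0.39 (0.0490), while mcs2 had -0.85 without replicate 4 and csk1 0.29 without replicate 3.

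Upstream of genes, in the 500 bp before the start codon, the values highest in Cy5 belonged to SPBC530.15C, a spermidine family transporter, at -2.11 ± 1.04 (SD, n = 2), SPCC4B3.13, a MatE family transporter, at -2.05, and byr2, a MAP kinase kinase kinase of the mating pathway, at -2.04. The splicing coactivator gene pwi1 (-1.84), the DNA polymerase kappa gene kpa1 (-1.82) and rpl2302 (-1.77) followed, with limma adjusted p from 0.00484 to 0.0101. The value upstream of SPCC4B3.13 turned direction after loess (0.19), in the deposited value table (0.65) and after loess with the GC correction (0.25). After loess the calls upstream of kpa1 (-0.07) and pwi1 (-0.69) were lost. In Cy3 SPBC216.03 was highest among genes with the same sign on all 4 arrays, at 1.46 (adjusted p = 0.0421), and iwr1 (1.39, 0.0512), vps17 (1.37, 0.0571), trk2 (1.35, 0.0571), SPBC21B10.09 (1.35, 0.074) and pku80 (1.31, 0.064) did not pass. The other Cy3 calls, chosen after their values were seen, were msk1, a lysyl-tRNA synthetase gene, at 1.53 and srb8, the gene of Mediator subunit Med12, at 1.45 ± 0.52 (adjusted p = 0.0483), each on 1 probe with no value on replicate 1.

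Of 4140 genes tested upstream, 19 were higher in Cy5 and 3 in Cy3, and the immunoprecipitations correlated at r = 0.24 across genes. The genes rpl2302, rps27, anc1 and ght8, chosen after their values were seen, were called in Cy5 both upstream and over the ORF, where 0.838 would be shared by chance. Counts were 0 in both directions after normexp, centring on the mode, the GC correction, in the deposited value table and with marked spots kept, with unadjusted limma counts in Cy3 and Cy5 of 309 and 161, 138 and 264, 284 and 178, 345 and 567, and 394 and 162 in that order. After loess they were 86 in Cy3 and 248 in Cy5, after loess with the GC correction 102 and 211. Without replicates 2, 3 and 4 the Cy5 count was 8, 7 and 48, and without replicates 1 to 4 the Cy3 count was 13, 1, 0 and 10, with 142 at an unadjusted p under 0.05 where it was 0; the value upstream of SPBC216.03 lost its call without replicate 1 (1.07), 2 (1.41) or 3 (1.85).

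Where along genes the signal lay was compared next. With the coding span in 10 equal parts, the mean over all genes was 0.11 in the fourth 100 bp upstream of the start, -0.11 in the ninth part of the body and -0.17 in the first 100 bp downstream. Ribosomal protein genes had -0.74 in the third part of the body (26 probes), -1.21 in the eighth (22 probes) and -1.21 in the first 100 bp downstream (66 probes), and -0.16 in the seventh 100 bp downstream (20 probes). After loess all genes were at -0.11, 0.04 and -0.17 in the same places, so the upstream and body values turned sign, and ribosomal protein genes were at -0.33, -0.56, -0.73 and -0.11 in theirs. Genes with a large gap between ORF and upstream were pdc101, at -2.18 over the ORF and 0.54 upstream, and ssa2, at -2.11 and 0.46, each with 1 upstream probe; these are the 2 genes of 3715 that limma called, both with the ORF higher in Cy5 (adjusted p = 0.0136).

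The median ORF minus upstream difference was -0.167 (95% interval -0.183 to -0.152), at -0.139 and -0.217 in the immunoprecipitations. Its sign depends on the scaling, being 0.121 after loess (0.102 to 0.147), 0.0935 in the deposited value table and 0.0629 after loess with the GC correction. By gene 0 were called with the ORF higher in Cy3, against 131 at an unadjusted p under 0.05, and after loess 188 in Cy3 and 53 in Cy5 were called; without replicates 1 and 4 the Cy5 count was 45 and 30, and without replicates 1, 3 and 4 the Cy3 count was 11, 2 and 19.

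**Figure D3:**
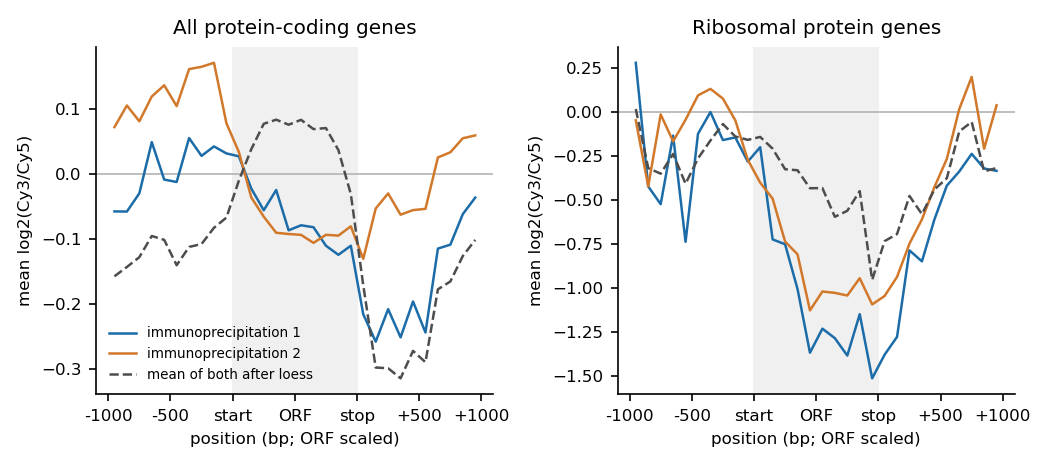
Mean log2(Cy3/Cy5) (y axis) by position along genes (x axis, in steps of 100 bp outside the coding span and in 10 equal parts within it, shaded) for all genes and for ribosomal protein genes, with a line per immunoprecipitation and a dashed line for the mean after loess. Ribosomal protein genes average -1.21 in the first 100 bp downstream, and -0.73 after loess.

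Intergenic regions were compared by the orientation of their flanking coding genes, to part promoters from gene ends. Convergent regions, which lie between the ends of both neighbours, were lowest, at -0.22 over 1947 probes in 916 regions. Tandem regions had -0.02 over 6133 probes in 1813 regions, and divergent regions, which lie between both starts, 0.11 over 4878 probes in 1128 regions. Divergent exceeded convergent regions by 0.338 (95% interval 0.296 to 0.379), at 0.368 and 0.309 in the immunoprecipitations, and tandem exceeded convergent regions by 0.205 (0.164 to 0.251). Both differences kept their sign after loess, at 0.251 and 0.152.

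**Figure D4:**
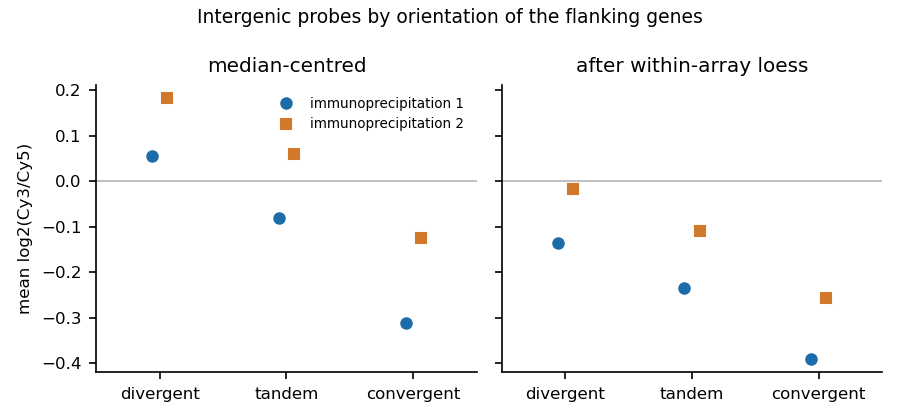
Mean log2(Cy3/Cy5) (y axis) of divergent, tandem and convergent intergenic regions (x axis), with a point per immunoprecipitation, median-centred on the left and after loess on the right. Convergent regions (-0.22) lie below tandem (-0.02) and divergent regions (0.11).

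Arrays of the same immunoprecipitation correlated across probes at a mean r of 0.238, and arrays of different immunoprecipitations at 0.231, and after loess at 0.428 and 0.420. Over ORFs the mean r was 0.375 and 0.371. With the spread taken from the technical duplicates, which covers technical noise only, limma called 0 of 32649 probes different between the immunoprecipitations, with 1635 at an unadjusted p under 0.05. Without replicate 3 the spread rests on replicates 2 and 4 alone, with replicate 1 assumed to vary like them. The counts were then 1076 probes with a higher ratio in the second immunoprecipitation and 245 with a lower one. Without replicate 1, where the same holds for replicate 3, the count was 2. Each side holds a single preparation. Probes and genes are not independent replicates.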

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

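Of the tests in this part, those on brightness and on GC content were chosen after the results were seen.

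In 8 of 142 results examined over the 4 arrays 1 array lay far from the other 3, where chance gives about 7.1, so their number is near that of chance. The Cy5 signal over negative controls was 14.052 on replicate 4, against 4.46 to 5.63 on the others. The median of the phosphate list was 0.12 on replicate 2, and that of the iron and copper list -0.0673 on replicate 3. Over ORFs, SPAC16C9.01C had 0.58 on replicate 2, ecm33 had -1.75 on replicate 4, ctr4 had -0.55 on replicate 1 and tpx1 had -2.53 on replicate 1. Upstream of pwi1 replicate 2 had -1.06.

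Of the first pattern, the higher Cy5 signal at ribosomal protein, glycolysis, chaperone, snRNA and snoRNA genes, a dye bias that grows with brightness is argued against as the whole cause, since the shift of ribosomal protein genes was -0.470 after loess, against -0.878 before it. A candidate explanation is that Cy5 holds the immunoprecipitated DNA, against the labels: corrected for GC content the Cy5 signal of these genes lay 0.607 above other ORFs (95% interval 0.501 to 0.728), and neighbouring probes correlated more in Cy5 than in Cy3 on 4 of 4 arrays. These lists were picked for their ratio on the same arrays, and the corrected signal spread more over probes in Cy5 (SD 0.81 to 1.12) than in Cy3 (0.46 to 0.53). A larger shift in Cy5 could thus arise whichever channel holds the immunoprecipitate, so the shift does not decide. Over all 5 lists the Cy3 signal lay at -0.153 (-0.224 to -0.0669). Depletion of Cy3-labelled DNA stays open for snoRNA genes, with -0.278 (-0.470 to -0.0947) in Cy3 and 0.466 (0.170 to 0.713) in Cy5. It stays open too for snRNA genes, with -0.510 (-0.948 to 0.0137) in Cy3 and 0.435 (-1.09 to 1.64) in Cy5. In Cy3 ribosomal protein genes had -0.0787 (-0.257 to 0.0035), glycolysis genes 0.02 (-0.17 to 0.25) and chaperone genes 0.00 (-0.12 to 0.11). Their Cy5 values were 0.689 (0.589 to 0.776), 1.05 (0.624 to 1.76) and 0.471 (0.299 to 0.786) in that order. For ribosomal protein, glycolysis and chaperone genes these values argue against depletion as the main source of the shift. Without an untagged sample, signal unrelated to Cdk11 also stays open, and no biological explanation was tested because there is 1 group.

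The second pattern is the higher Cy5 signal of convergent against divergent intergenic regions. GC content is argued against as the whole cause, with a difference of 0.344 (0.302 to 0.385) after the GC correction, and so is brightness, with 0.251 (0.220 to 0.285) after loess. Spread from neighbouring genes high in Cy5 stays open. Without regions beside the 421 genes with the lowest ORF values 0.250 (0.214 to 0.288) was left, against 0.338 over all regions. Those genes alone thus do not account for the whole difference, though regions beside them differed by 0.555. Genes just short of that cut stayed in as neighbours, so the test does not decide on spread as a whole. No biological explanation was tested.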

How the results depend on the processing

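Keeping the marked spots, subtracting the local background and loess with the GC correction were chosen after the results were seen. Counts are given as higher in Cy3 and higher in Cy5, and the cause of each change was not tested unless its construction shows it (other thresholds, run lengths, windows or fewer arrays). Between 8 and 13 lists were called in Cy5 in all settings but the estimated correlation. With upstream values they were 8. Of these, the tRNA, snRNA, snoRNA and rRNA lists kept their own gene values, and only the comparison genes changed. Called on upstream values were ribosomal proteins, membrane ATPase and transporter genes, phosphate and core histones, while 5 lists lost the call and chaperones turned. Both intergenic differences kept their sign in all settings, at 0.216 to 0.450 and 0.123 to 0.271. Cy5 signal over background limits replicate 1, where it passed at 80.2% of probes. Slide or scan as a block was not run, since the files used here give neither. No paired analysis was possible because the arrays form 1 group. Centring on the mode moved the median ORF value of all genes by -0.157, other scalings by at most 0.0855.

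Normexp gave 600 probes in Cy5, 3353 and 4330 by fold, 56 regions in Cy3, 57 ORFs in Cy3, 0 and 0 upstream (309 and 161 at an unadjusted p under 0.05 by limma), and 4 and 19 for ORF minus upstream. Loess gave 1706 and 2806 probes, 24 and 96 regions, 275 ORFs in Cy3, 86 and 248 upstream, 188 and 53 for the difference with a median of 0.121, 1 list in Cy3 (cell adhesion, 0.24), and r of 0.428 and 0.420. The mode gave 34 and 1484 probes, 883 by fold in Cy3, 3 regions in Cy3, 0 ORFs in Cy3 (45 unadjusted), 0 and 0 upstream (138 and 264 unadjusted) and 21 and 83 for the difference. Probes well above background gave 8 regions, 49 ORFs and 11 upstream in Cy3, and 16 and 44 for the difference. The deposited value table gave 2276 and 3208 probes, 23 and 92 regions, 39 and 62 ORFs, 0 and 0 upstream (345 and 567 unadjusted), 256 and 99 for the difference with a median of 0.0935, 1 list in Cy3 (cell adhesion, 0.23), and r of 0.418 and 0.408. The GC correction gave 40 ORFs in Cy3 and 0 and 0 upstream (284 and 178 unadjusted).

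Marked spots kept gave 170 probes and 4 ORFs in Cy3, 0 and 0 upstream (394 and 162 unadjusted), 27 and 130 for the difference and 1 list in Cy3. Subtracting the local background gave 34 regions and 12 upstream in Cy3, 11 and 38 for the difference and 1 list in Cy3. Loess with the GC correction gave 1283 and 2345 probes, 81 regions in Cy5, 186 ORFs in Cy3, 102 and 211 upstream, 46 and 18 for the difference with a median of 0.0629, and 1 list in Cy3 (cell adhesion, 0.21).

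With the immunoprecipitation as a random block there were 351 and 1555 probes, 38 ORFs in Cy3, 37 and 50 upstream and 27 and 117 for the difference. With 4 arrays as independent there were 12 ORFs and 1 upstream in Cy3 and 11 and 40 for the difference. With a variance trend and robust fit there were 0 and 498 probes (2336 and 2846 unadjusted), 0 ORFs in Cy3 (69 unadjusted), 0 and 0 upstream (389 and 78 unadjusted) and 0 in Cy5 for the difference (443 unadjusted).

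A 2-fold limit gave 159 and 971 probes and 0 and 90 regions, and the looser limit 4709 and 5671 probes and 129 and 383 regions. Runs of at least 5 probes gave 0 and 74 regions, and of at least 2 probes 127 and 446. The median of ORF probes gave 3 and 111 ORFs, and any ORF probe 42 in Cy3. Upstream windows of 300 bp gave 5 in Cy3 and 4 and 8 for the difference, and of 1000 bp 39 and 99 upstream. The estimated correlation, which almost no list could pass with 2 immunoprecipitations, left 0 lists in Cy5. Rotation along the genome called 1 list in Cy3, the long non-coding RNA genes, and added phosphate in Cy5.

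Leaving out 1 array or immunoprecipitation gave 1 to 90 and 274 to 783 probes by test, 1631 to 8400 and 2634 to 10014 by fold, 11 to 540 and 171 to 758 regions, 3 to 21 and 99 to 165 ORFs, 0 to 13 and 7 to 48 upstream, 0 to 19 and 2 to 45 for the difference, and 0 to 1 lists in Cy3. With an immunoprecipitation left out, the counts by fold and of regions need the fold only in the remaining 1. Their upper ends therefore come from a looser rule. Between immunoprecipitations, against technical noise only, it gave 0 to 1076 probes higher and 0 to 245 lower in the second.

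Of 2150 values of named genes under alternatives 1890 kept the call or its absence, 55 of them uncalled with the other sign, 196 lost the call, 59 gained it and 5 reversed. The kept ones include 104 values for each immunoprecipitation left out, where no test could be run and no call could be lost or gained. Of 437 list values 399 kept the call or its absence, 27 of them uncalled with the other sign, 24 lost the call, 10 gained it and 4 reversed. Here too the kept ones include 23 untested values for each immunoprecipitation left out. Of 183 values of the longest regions 134 moved by less than the spread and 49 by more. The reversals were gsf2 at 0.48 after loess and 0.40 with the GC correction added, upstream SPCC4B3.13 at 0.19 after loess, 0.65 in the deposited value table and 0.25 after loess with the GC correction, the cell adhesion list as above, and chaperones at 0.0631 with upstream values.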

Other observations

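The test on codon usage was written down before its result was seen, and the comparisons of the unnamed stretch and of genes with introns were chosen after the results were seen.

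On the stretch of chromosome I where no gene could be named, 38 regions were higher in Cy5 over 6236 probes, or 6.09 per 1000 probes, against 164 over 36405 probes, or 4.50 per 1000, elsewhere. The longest of them reached 5.06-fold over 17 probes. The 66 mitochondrial probes had a mean of 0.53, at 0.96 and 0.09 in the immunoprecipitations, and 2.57 after loess, so this value follows the scaling. By array it was 1.27, 0.57, 0.65 and -0.38 on replicates 1 to 4, of opposite signs within the second immunoprecipitation, and without replicate 2 the mean was 0.29. Genes with introns had a median ORF value of 0.00 (1759 genes) and those without -0.05 (1842 genes), and the order turned after loess, at 0.03 and 0.07.

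A hypothesis is that ORF values outside the fixed lists may follow transcript level, as read from the codon adaptation of each gene. Genes found only in the subtelomeric list were kept in this test. Across 3601 genes, which are not independent replicates, Spearman's rho corrected for GC content was -0.163 (95% interval -0.197 to -0.128), at -0.143 and -0.137 in the immunoprecipitations. After loess it was -0.0873, short of the bound of -0.1 set before the test but not near 0, so the test does not decide. The tenth part of genes with the highest codon adaptation had a median of -0.24 and the lowest 0.05, against -0.04 and 0.04 after loess.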
